A study of Mus musculus with 21 samples.

How the data were processed

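Single-cell RNA was measured in kidney, lung and spleen of 7 male C57Bl/6 mice, 4 young and 3 old, which gave 21 samples in 39 droplet lanes (10x Genomics, 3' chemistry). Per the labels, the authors aligned reads to mm10 and counted molecules with Cell Ranger 3.0.2. The deposited matrices held raw UMI counts (whole numbers per gene and barcode), without normalization by the authors, for 28691 genes in 90582 barcodes. Lanes of a sample were summed, and no 2 lanes held the same values. Gene identifiers and symbols were taken from the deposited gene tables, and coordinates from GENCODE vM21 (mm10) by identifier, which matched 502 of 507 genes looked up.

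Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs in lung and spleen or 50% in kidney, whose tubule cells are rich in mitochondria. Simulated doublets were mixed into each lane, and the barcodes most like them were removed at a rate of 0.8% per 1000 barcodes, 1273 in all. Each tissue was clustered over all animals (2000 variable genes, 40 principal components, 20 neighbours, Leiden resolution 1, no batch integration; leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, Python 3.11.15), and clusters were named from 48 marker lists. In all, 72501 cells were kept. Free RNA was not modelled, so a gene abundant in another cell type of the same suspension could enter a class, and genes with under 0.25 of their tissue mean in a class were not chosen for naming.

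UMI counts of a class were summed per animal, animals with under 20 cells of it were left out, and a class was tested where at least 3 young and 3 old animals remained. Old was compared with young by the edgeR 4.0.16 quasi-likelihood test with TMM scaling and filterByExpr in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. Changes are log2 fold changes of old over young, and levels are CPM, counts scaled to the same library total, as mean and SD over animals. Differences between tissues in the age effect were tested with the age by tissue term, with animal as a block. For this test all T cell classes were summed.

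Gene lists, 33 in number, were tested with camera of limma 3.58.1 (log2 CPM, prior count 2, preset correlation of 0.01, at least 5 tested members), adjusted over the lists of a class. Camera asks whether a list moved relative to the other genes. With a correlation estimated from these few animals, camera called 0 lists in each tissue, so every list call in the text rests on the preset correlation. The fry test asks whether the members moved on balance one way, without a comparison with other genes; it called 3 lists by class in kidney, 7 in lung and 10 in spleen. The median change of a list had the sign of its test in all called lists but 1, the abundant lung epithelial transcripts in lung T cells, whose median was -0.27, whose mean was 0.26 and whose test was upward (adjusted p = 0.0139, and 0.436 without young 1). Its adjusted p was 0.436 at most over the fits without 1 animal.

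Shares of cells and cell-to-cell distances were compared by exact permutation of the 7 animals, two-sided, over 35 splits; the smallest p is 0.0286, or 0.1 for 3 against 3. Chance puts all old animals on 1 side of all young ones in 5.71% of splits (10% for 3 against 3). The distance of an animal was the median over its cells, thinned to 1000 UMIs, of 1 minus the Spearman correlation with the mean of the other cells over 500 genes.

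Genes were named by a rule written, like the lists and tests, before the data were examined. It took per tissue up to 8 genes called in the same direction in the most classes (at least 2), and in the 4 most abundant tested classes the 3 genes higher and the 3 lower with the largest change among called genes with no overlap between groups, at least 50 CPM and the limit on free RNA. It also took up to 4 members, by smallest p, of each called list in those classes. The 4 classes were proximal tubule, endothelial cells, macrophages and B cells in kidney, endothelial cells, fibroblasts, B cells and T cells in lung, and B cells, CD4 T cells, CD8 T cells and dendritic cells in spleen. Other genes are marked as chosen after their values were seen.

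Alternatives were DESeq2 1.42.0, RLE scaling, no gene filter, stricter cell filters, doublets kept, the first lane alone, at most 100 cells per animal and class, Leiden resolution 2, replicate number as a block, camera with an estimated correlation, fry, other distance settings, edgeR on cell counts and leaving out each animal in turn. Added after seeing the data were a second term for a split of the animals other than by age, B cells without clusters 4 and 7, and scaling by library totals. Simulated counts with the library totals, levels and spread of the real sums tested the fits, with 200 genes per class changed. Of genes changed 2-fold, 47.3% were recovered in kidney, 42.9% in lung and 61.2% in spleen, and of those changed 4-fold 92.4%, 88.8% and 94.2%. For the age by tissue term these were 4.75% and 53.8% for kidney against lung, 17.0% and 58.0% for kidney against spleen, and 19.3% and 73.3% for lung against spleen. Between 5.44% and 7.98% of the simulated calls were of unchanged genes. A list raised 1.5-fold was called in 9 of 9 kidney, 14 of 14 lung and 6 of 6 spleen classes. Of the other lists 0 of 198, 1 of 329 and 0 of 132 were called. The simulated genes varied independently of each other, so this cannot show how often correlated genes give list calls. In the real data, splits of the animals other than by age gave up to 76, 97 and 50 list calls.

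Intervals on shares of single samples are 95% Wilson intervals, a count of 0 is given with the limit of 3 counts, and both cover counting error only. Barcodes below the filters and classes with too few cells were left out of the tests. Lanes, days and sequencing runs were not labelled as batches, so none could be tested.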

Results

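The samples came from 4 young mice (29, 31, 34 and 34 weeks) and 3 old mice (88, 91 and 93 weeks), each of which gave kidney, lung and spleen. Kidney and lung were digested with liberase, an enzyme blend, and spleen was dissociated mechanically. Each lane was loaded with 6000 cells, and samples had 2 lanes except spleen of young 1, kidney of old 3 and lung of old 3, which had 1. Total UMI counts per sample ran from 8738522 to 19050258 in kidney, from 8743509 to 21949416 in lung and from 3898868 (young 1) to 19485476 in spleen. The filters kept 13827 kidney, 29046 lung and 29628 spleen cells, with sample medians of 1694 to 4797.5 UMIs per cell. Kidney of old 1 kept 15.8% of its barcodes (95% interval 15.1% to 16.6%). Its first lane kept 1409 of 1871 barcodes, and its second kept 0 of 7022, with a median of 1 UMI. The other kidney samples kept from 44.8% (young 4) and 50.5% (young 3) to 77.6% (old 2). Before filtering, the median mitochondrial share per kidney barcode ran from 21.8% to 66.2% over the young lanes. Over the old lanes with kept cells it ran from 5.20% to 26.3%. Whether this uneven loss bears on the kidney comparisons was not tested. The comparisons asked how transcription within each cell type, the make-up of each tissue and the spread between cells differed with age, and whether the age effect differed between tissues.

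The library labelled young 1 lung held almost no transcripts of lung epithelium. Sftpc, a surfactant protein gene of type II pneumocytes, stood at 1.96 CPM (95% interval 1.41 to 2.71), against 4516 to 27200 CPM in the other 6 lung libraries. Sftpb stood at 0.163 CPM against 365 to 1870, Ager, a gene of type I pneumocytes, at 0.925 CPM against 354 to 1387, and Scgb1a1, a gene of club cells, at 3.10 CPM against 8442 to 53353. It held 0 alveolar macrophages, 0 ciliated cells, 0 club cells and 0 type I or type II pneumocytes among 3500 cells, which allows a share of up to 0.0857% for each. Fibroblasts made up 44.6% of its cells (95% interval 43.0% to 46.3%). Heart muscle genes were present, with Nppa, which encodes a peptide hormone of the atria, at 50.2 CPM against at most 0.137, and Myl2 at 51.7 CPM against at most 1.55. The totals of called genes and lists in lung and the lung shares named in the text are therefore also given without this library, a choice made after seeing the data.

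**Figure D1:**
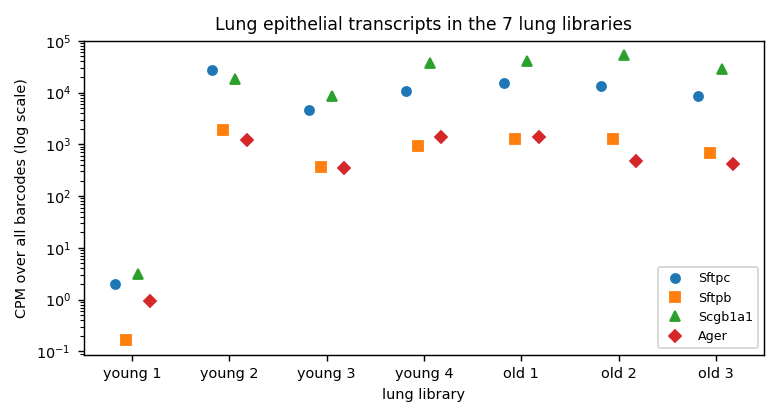
CPM of epithelial genes in each of the 7 lung libraries on a log axis, 1 point per gene and library, with genes in separate colours and shapes. The library labelled young 1 lung holds 1.96 CPM of Sftpc, and the other 6 hold 4516 to 27200 CPM.

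In kidney, T cells of old mice had fewer transcripts of Ccr7 (ENSMUSG00000037944, mm10 chromosome 11, 99144196 to 99155077), the receptor that guides naive T cells to lymph nodes. Ccr7 fell from 131 CPM ± 12.2 (SD, n = 4) to 38.3 CPM ± 8.21 (SD, n = 3), a log2 fold change of -1.89 (adjusted p = 0.00251). Without each animal in turn its adjusted p ran from 0.00171 to 0.0295. The naive T cell list fell in kidney T cells (adjusted p = 1.59e-08; adjusted p = 0.107 with an estimated correlation). Of its 15 tested members 12 were negative, 5 called over all genes and 7 when adjusted over the list alone. The 5 were Ccr7, Dapl1, Satb1, S1pr1 and Igfbp4, chosen after their values were seen, and they were all of the genes called lower in this class. S1pr1, a receptor that lets T cells leave lymphoid tissue, fell from 112 CPM ± 25.1 to 47.2 CPM ± 3.03 (log2 -1.39, adjusted p = 0.0337). Its call was kept without young 2 (0.0325) and lost without young 1 (0.0657), young 3 (0.0612), young 4 (0.256), old 1 (0.12), old 2 (0.177) and old 3 (0.0715). The call of Dapl1 was lost without young 4 (0.0527) and old 2 (0.0570), and that of Satb1 without young 1 (0.0755), young 4 (0.171), old 1 (0.0869) and old 2 (0.133). Igfbp4 lay under the limit on free RNA, and its call was lost without old 1 (0.0759) and old 2 (0.133). The interferon response list rose in the same cells (adjusted p = 5.20e-10; adjusted p = 0.255 with an estimated correlation). Of its 29 members 28 were positive, 0 called over all genes and 2 over the list alone. MHC class II genes rose more in these T cells (log2 1.00 against 0.52, medians relative to all genes). Mitochondrially encoded transcripts fell (-0.48 on the same scale).

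Kidney macrophages of old mice held more Lyz1 (ENSMUSG00000069515, mm10 chromosome 10, 117287797 to 117292868), a lysozyme gene, at 227 CPM ± 143 against 10.1 CPM ± 6.83 in young mice (log2 4.27, adjusted p = 0.0144). Reads of Lyz1 are hard to tell from those of its close paralog Lyz2, so the assignment to Lyz1 is uncertain. The call was lost without young 2 (adjusted p = 0.0715) and without young 4 (0.124), and over all alternatives its adjusted p ran from 6.37e-52 to 0.124. Heat shock chaperones fell in macrophages (adjusted p = 1.33e-12; adjusted p = 0.310 with an estimated correlation). Of its 16 members 15 were negative, 0 called over all genes and 12 over the list alone. Hspa1a, an inducible chaperone, stood at 7125 CPM ± 866 in young and 4152 CPM ± 324 in old, and Hspa1b at 507 CPM ± 162 and 200.1 CPM ± 28.3. The same list fell in 7 of 9 kidney classes, and in 5 to 8 classes without 1 animal. Cytosolic ribosomal protein genes fell in macrophages (adjusted p = 1.33e-12; adjusted p = 0.679 with an estimated correlation). Of its 81 members 79 were negative. They fell in 4 of 9 kidney classes and rose in 1, or fell in 2 and rose in 2 without old 2.

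Kidney B cells of old mice were higher in the age-associated B cell list (adjusted p = 2.28e-07; adjusted p = 0.0527 with an estimated correlation). Of its 8 members 8 were positive, 0 called over all genes and 4 over the list alone. Cluster 17 held 4.81% ± 2.80 of the kidney B cells of young mice and 20.2% ± 11.5 of those of old mice (33.4% in old 2). Of the members of the age-associated list Apoe stood at 371 CPM ± 26.1 in young and 989 CPM ± 656 in old. Zbtb20, a transcription factor, stood at 121 CPM ± 17.1 and 250 CPM ± 102. The T cell effector memory list rose in the same B cells, by a median log2 of 0.79. The age-associated list rose by 0.87, both relative to all genes. In proximal tubule cells the list of tubule injury genes rose (adjusted p = 0.00397; adjusted p = 0.257 with an estimated correlation). Of its 7 members 7 were positive and 0 called over all genes or over the list alone. Its member Spp1, which encodes osteopontin, stood at 194 CPM ± 60.3 in young and 388 CPM ± 249 in old. The injury call was lost without young 2, young 4 or old 1, where its adjusted p reached 0.558. The list was not particular to these cells. It was called upward in 5 of 7 kidney classes, with a median log2 change of 0.35 in proximal tubule, 0.59 in loop of Henle, 0.48 in endothelial cells, 0.30 in macrophages and 0.24 in stromal cells. That count was 1 without young 2, 2 without old 1 and 3 without each of the others. The largest of the 4 clusters of proximal tubule cells was cluster 4 in young mice (26.8% ± 10.7, and 25.5% ± 16.3 in old) and cluster 1 in old mice (33.2% ± 18.8, and 22.7% ± 10.8 in young).

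Over the 9 kidney classes edgeR called 4 genes higher and 5 lower in old mice, in T cells (1 and 5), macrophages (2 and 0) and proximal tubule (1 and 0). The other genes called higher were Igkc in T cells, Id3 in macrophages and Igha in proximal tubule, named after their values were seen, and all 3 lay under the limit on free RNA. Igkc was not called without young 1 (0.0657), young 2 (0.0611), young 4 (0.132) and old 2 (0.0524). Id3 was not called without young 2 (0.0761), young 4 (0.215), old 2 (0.0559) and old 3 (0.114), and Igha without young 3 (0.142). In the 6 classes with 0 calls, genes at an unadjusted p under 0.05 numbered 262 in B cells, 183 in distal convoluted tubule, 719 in endothelial cells, 162 in loop of Henle, 117 in nonclassical monocytes and 221 in stromal cells. Of simulated 2-fold changes 7.00% were recovered in stromal cells, and 48.0% to 61.0% in the others of these classes. DESeq2 called 4 higher and 1 lower in B cells, 21 and 15 in endothelial cells, 0 and 1 in nonclassical monocytes, 1 and 2 in stromal cells, and 0 in distal convoluted tubule and loop of Henle. Without young 1, 2, 3 and 4 the kidney counts were 14, 3, 29 and 2 higher and 16, 5, 12 and 1 lower. Without old 1, 2 and 3 they were 9, 76 and 37 higher and 2, 10 and 36 lower. Calls kept without each animal in turn were 1 of 6 in T cells, 0 of 2 in macrophages and 0 of 1 in proximal tubule. Of the list tests 72 of 208 were called, 46 upward and 26 downward, 0 of them with an estimated correlation. With free-RNA genes left out 27 were upward and 23 downward, and without old 1 there were 26 and 33.

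In lung, T cells of old mice held more Il17a (ENSMUSG00000025929, mm10 chromosome 1, 20730905 to 20734496), a cytokine that draws neutrophils, at 91.9 CPM ± 15.1 (SD, n = 3) against 7.95 CPM ± 5.40 (SD, n = 4; log2 3.32, adjusted p = 0.000521). Cxcl10, a chemokine induced by interferon, rose from 12.0 CPM ± 2.14 to 50.1 CPM ± 8.64 (log2 1.97, adjusted p = 0.00939). Both were chosen after their values were seen, and both were called without each animal in turn, with adjusted p of at most 0.00603 and 0.0479. Of the 12 T cell calls they were the only 2 kept in every such fit. Of the genes named by rule, Serpina3g, a protease inhibitor of activated T cells, rose from 27.7 CPM ± 5.53 to 75.7 CPM ± 7.04 (log2 1.42, adjusted p = 0.0121). Gzmm, a granzyme, rose from 24.5 CPM ± 10.4 to 99.9 CPM ± 27.5 (log2 1.81, adjusted p = 0.0237). Klrk1, the receptor NKG2D, rose from 71.2 CPM ± 7.12 to 154 CPM ± 20.5 (log2 1.05, adjusted p = 0.0314). Igfbp4 fell from 143 CPM ± 18.1 to 49.5 CPM ± 15.1 (log2 -1.57, adjusted p = 0.0121), and the chemokine gene Cxcl2 from 98.7 CPM ± 33.6 to 24.2 CPM ± 10.3 (log2 -2.09, adjusted p = 0.0123). Each of these 5 calls was kept without young 1. That of Serpina3g was lost without young 2 (0.0687), young 3 (0.0721) and old 1 (0.0648). That of Gzmm was lost without young 3 (0.161), young 4 (0.124), old 1 (0.114) and old 3 (0.12). That of Klrk1 was lost without young 2 (0.129), young 3 (0.171), young 4 (0.124), old 1 (0.216), old 2 (0.0542) and old 3 (0.138). Igfbp4 lost its call without old 1 (0.0658) and old 2 (0.0883), and Cxcl2 without young 3 (0.0721), old 2 (0.0840) and old 3 (0.0507). All 5 lost their call on the first lane alone (adjusted p from 0.0516 to 0.291) and with at most 100 cells (0.269 to 0.515), and Gzmm (0.115) and Klrk1 (0.2) with replicate number as a block. At Leiden resolution 2 the change of Cxcl2 was log2 -0.25 (0.934). Cxcl2 and Igfbp4 lay near the limit on free RNA, at 66.8 and 103 CPM in T cells and 267 and 382 CPM in the tissue. Lists of other cell types fell in the same T cells, collagen and matrix by a median log2 of -1.39 (adjusted p = 1.50e-05; adjusted p = 0.197 with an estimated correlation) and endothelial genes by -0.66 (adjusted p = 0.00812; adjusted p = 0.340 with an estimated correlation). The endothelial call was lost without young 2 and young 4, where its adjusted p reached 0.134.

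The effector memory list rose in lung T cells (adjusted p = 1.14e-06; adjusted p = 0.0777 with an estimated correlation). Of its 29 members 23 were positive and 2 called over all genes, while adjusted over the list alone 9 were higher and 1 lower. Nkg7, a gene of cytotoxic granules, stood at 438 CPM ± 103 in young and 826 CPM ± 65.5 in old. The naive T cell list fell (adjusted p = 6.62e-05; adjusted p = 0.360 with an estimated correlation). Of its 16 members 12 were negative and 1 called over all genes. Lef1, a transcription factor of naive T cells, stood at 243 CPM ± 29.6 and 129.95 CPM ± 46.0. The largest cluster of lung T cells in young mice was 13 (47.7% ± 7.62), which held 15.5% ± 4.63 in old mice, whose largest cluster was 10 (41.7% ± 2.30). Cluster 9, whose markers match gamma delta T cells, held 27.2% ± 2.73 in young and 41.4% ± 6.29 in old mice without overlap. Whether the change of Il17a followed this make-up was not tested. In lung B cells Pld4 rose from 73.1 CPM ± 11.5 to 169 CPM ± 47.2 (log2 1.15, adjusted p = 0.0447). Its call was kept without young 1 (0.00582) and old 1 (0.0168) and lost without young 2 (0.218), young 3 (0.105), young 4 (0.251), old 2 (0.180) and old 3 (0.0707). The age-associated B cell list rose there (adjusted p = 1.27e-05; adjusted p = 0.312 with an estimated correlation). Of its 13 members 11 were positive, 0 called over all genes and 6 over the list alone. Cluster 17 held 5.05% ± 1.32 of the lung B cells of young mice and 23.0% ± 11.1 of those of old mice (35.7% in old 2). Apoe stood at 459.8 CPM ± 191 in young and 1281 CPM ± 662 in old.

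Type II pneumocytes, the surfactant cells of the alveoli, were compared in 3 young and 3 old mice, since the library labelled young 1 lung held 0. The genes in this paragraph were chosen after their values were seen, except Mt2, Areg and Mt1, which the rule named. Lrg1 (ENSMUSG00000037095, mm10 chromosome 17, 56119678 to 56122001), a secreted glycoprotein, rose from 344 CPM ± 47.9 to 677 CPM ± 16.6 (log2 1.08, adjusted p = 0.00307). Lcn2, a siderophore-binding protein of innate defence, rose from 874 CPM ± 91.9 to 1628 CPM ± 407 (log2 1.00, adjusted p = 0.00494). The metallothionein Mt2 (ENSMUSG00000031762, mm10 chromosome 8, 94172664 to 94173568) fell from 396 CPM ± 118 to 116 CPM ± 26.5 (log2 -1.64, adjusted p = 0.00307). Areg, an epidermal growth factor family ligand, fell from 287 CPM ± 64.2 to 83.4 CPM ± 56.9 (log2 -1.81, adjusted p = 0.00946). All 4 calls were kept without each animal in turn. The call of Areg was lost with DESeq2 (0.0802), and on the first lane alone the adjusted p was 0.0601 for Areg and 0.0717 for Mt2. Mt1 fell too (981 CPM ± 350 to 454 CPM ± 94.8, log2 -1.02, adjusted p = 0.0216), and its call was lost without old 2 (0.0932) and on the first lane alone. The immediate early list fell (adjusted p = 2.73e-14; adjusted p = 0.462 with an estimated correlation). Of its 24 members 24 were negative, 8 called over all genes and 16 over the list alone. Among those called were Jund (1387 CPM ± 133 to 705 CPM ± 68.5) and Egr1 (875 CPM ± 99.8 to 440.1 CPM ± 91.9). These genes respond to tissue handling as well as to signals in the animal. A second term for another split of the animals, young 1, old 1 and old 2 against the rest, was added after seeing the data. In these cells, where young 1 is absent, it leaves the age change to old 3 against the young mice. The change was then log2 -1.56 for Mt2, 1.05 for Lrg1, -0.82 for Areg, 1.36 for Lcn2 and -0.71 for Mt1. With 1 old animal these values cannot say whether the calls depend on that split.

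Alveolar macrophages, also compared 3 against 3, held more Cxcl2 in old mice (347 CPM ± 36.4 to 935 CPM ± 270.4, log2 1.48, adjusted p = 0.00198). H2-Eb1, an MHC class II gene, rose from 484 CPM ± 48.8 to 872 CPM ± 83.4 (log2 0.88, adjusted p = 0.00646). Both were chosen after their values were seen and were called without each animal in turn. The second term for another split leaves the age change here to old 3 against the young mice. With it the change of Cxcl2 was log2 0.84 and that of H2-Eb1 0.70. The histone variant gene H3f3b, named by rule, fell in alveolar macrophages (2949.6 CPM ± 355 to 1798 CPM ± 238, log2 -0.69, adjusted p = 0.0190). It also fell in classical monocytes (4325 CPM ± 366 to 2698 CPM ± 512, log2 -0.73, adjusted p = 0.0489) and dendritic cells (log2 -0.64, adjusted p = 0.0436). In alveolar macrophages its call was lost without young 2 (0.0968), young 4 (0.0712), old 1 (0.0903) and old 2 (0.126). In monocytes and dendritic cells it was kept without old 3 alone (0.00366 and 0.00236). In monocytes its adjusted p was 0.0663, 0.145 and 0.258 without young 2, 3 and 4 and 0.133 and 0.0979 without old 1 and 2, and in dendritic cells, in the same order, 0.0615, 0.0815, 0.210, 0.147 and 0.223. Mt2 fell in dendritic cells as well (618 CPM ± 125 to 298 CPM ± 31.9, log2 -1.10, adjusted p = 0.0129), a call lost without old 2 (0.0930). Rsrp1 rose in classical monocytes (166 CPM ± 46.3 to 571 CPM ± 194, log2 1.72, adjusted p = 0.0151), a call lost without young 4 (0.0983). With the second term the change of H3f3b was log2 -0.52, -0.45 and -0.40 in the 3 classes, that of Mt2 -0.88 and that of Rsrp1 1.20. Young 1 is absent from all 3 classes, so these values rest on old 3 as the only old animal.

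Lung fibroblasts of old mice were lower in collagen and matrix genes (adjusted p = 1.45e-08; adjusted p = 0.592 with an estimated correlation; adjusted p = 2.57e-07 without young 1). Of its 36 members 32 were negative and 0 called over all genes or over the list alone. Col14a1 stood at 91.4 CPM ± 23.3 in young and 52.4 CPM ± 14.1 in old, and Timp1, an inhibitor of matrix proteases, at 144 CPM ± 49.6 and 69.3 CPM ± 16.4. The list was called downward in 7 of 9 lung classes, and in 4 of 9 without young 4. Its median log2 change was -0.56 in fibroblasts, -1.74 in B cells, -1.39 in T cells and -1.14 in endothelial cells. Other lists fell in fibroblasts too, endothelial genes by -0.64, the T cell effector memory list by -0.30 and mitochondrially encoded transcripts by -0.28. These are medians relative to all genes, by which collagen and matrix stood at -0.55. Free RNA of fibroblasts, whose mean share was 21.9% in young and 8.01% in old lungs, was not modelled. Of the fibroblasts of young 1, 98.4% lay in cluster 4, which held at most 4.46% in the other animals, and the largest cluster was 6 in young and 8 in old mice. Over the 14 lung classes edgeR called 64 genes higher and 82 lower in old mice, and 148 and 158 without the library labelled young 1 lung. The calls lay in type II pneumocytes (18 higher, 31 lower), dendritic cells (6 and 22), classical monocytes (4 and 20), alveolar macrophages (17 and 4), T cells (8 and 4), B cells (9 and 0) and NK cells (2 and 1). In the classes with 0 calls, 554 genes in endothelial cells, 659 in fibroblasts, 181 in macrophages, 106 in neutrophils, 349 in nonclassical monocytes, 267 in smooth muscle or pericytes and 170 in ciliated cells had an unadjusted p under 0.05. DESeq2 called 0 in endothelial and ciliated cells, 4 higher and 2 lower in fibroblasts, 0 and 1 in macrophages, 3 and 6 in neutrophils, 1 and 2 in nonclassical monocytes, and 1 and 1 in smooth muscle or pericytes. Without young 2, 3 and 4 the lung counts were 32, 27 and 48 higher and 79, 50 and 42 lower. Without old 1, 2 and 3 they were 67, 50 and 113 higher and 54, 18 and 212 lower. Calls kept without each animal in turn were 14 of 49 in type II pneumocytes, 3 of 21 in alveolar macrophages and 2 of 12 in T cells. They were 1 of 3 in NK cells, 0 of 28 in dendritic cells, 0 of 24 in classical monocytes and 0 of 9 in B cells. Of the list tests 109 of 349 were called, 52 upward and 57 downward, 0 of them with an estimated correlation. Without young 1, 58 were upward and 50 downward, without young 2 there were 53 and 37, and without young 4 there were 59 and 29. Under the second term lung T cells kept 12 of 12 calls, B cells 7 of 9 and NK cells 1 of 3. Kidney kept 3 of 9 with it. Spleen B cells kept 17 of 117, CD8 T cells 30 of 57, NK cells 4 of 13 and CD4 T cells 2 of 7. All calls of age kept their sign. Classes fitted without young 1 are left out of these counts, since the term leaves them old 3 alone against the young mice.

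In spleen, CD8 T cells of old mice had 39 genes called higher and 18 lower. Klrc1 (ENSMUSG00000030167, mm10 chromosome 6, 129666015 to 129678973), which encodes the inhibitory receptor NKG2A, rose from 50.2 CPM ± 12.5 (SD, n = 4) to 144 CPM ± 39.1 (SD, n = 3; log2 1.28, adjusted p = 0.00105). Serpina3g (ENSMUSG00000041481, mm10 chromosome 12, 104236245 to 104241939) rose from 46.1 CPM ± 8.67 to 108 CPM ± 19.1 (log2 1.13, adjusted p = 0.000484). Fcgrt (ENSMUSG00000003420, mm10 chromosome 7, 45092990 to 45103851), which encodes the neonatal Fc receptor, rose from 58.3 CPM ± 13.4 to 156 CPM ± 6.52 (log2 1.19, adjusted p = 0.000874). These 3 genes were called under each of 18 alternatives that were run for them. Id3, a transcription regulator (ENSMUSG00000007872, mm10 chromosome 4, 136143497 to 136145755), fell from 72.5 CPM ± 8.23 to 35.9 CPM ± 8.22 (log2 -1.10, adjusted p = 0.00251). It kept its call without each animal in turn and lost it on the first lane alone (0.353) and with at most 100 cells (0.298). Dapl1, a gene of naive CD8 T cells, fell from 400.1 CPM ± 51.8 to 194 CPM ± 67.4 (log2 -1.13, adjusted p = 0.00638). Trdc, the constant region of the T cell receptor delta chain, fell from 96.9 CPM ± 16.6 to 39.3 CPM ± 18.1 (log2 -1.25, adjusted p = 0.00684). Both calls were lost without old 1 (0.0744 and 0.0699). For Trdc the change was log2 -1.004 on the first lane alone (0.273) and -0.11 with at most 100 cells (0.980).

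The effector memory list rose in spleen CD8 T cells (adjusted p = 4.03e-16; adjusted p = 0.0587 with an estimated correlation). Of its 27 members 26 were positive, 10 called over all genes and 19 over the list alone. Lists of B cells rose in the same CD8 T cells. Abundant B cell transcripts rose by a median log2 of 0.35 (adjusted p = 0.00228; adjusted p = 0.194 with an estimated correlation) and immunoglobulin genes by 0.40 (adjusted p = 0.00373, and 0.230 without old 1; adjusted p = 0.426 with an estimated correlation). The age-associated B cell list rose by 0.50 (adjusted p = 4.28e-05; adjusted p = 0.0587 with an estimated correlation). Ccl5, a chemokine of memory CD8 T cells, rose from 6426 CPM ± 2373 to 14906 CPM ± 1879 (log2 1.08, adjusted p = 0.0128), a call lost without young 2 (0.0887), old 1 (0.0665) and old 2 (0.0655). The naive T cell list fell (adjusted p = 6.56e-05; adjusted p = 0.194 with an estimated correlation). Of its 17 members 12 were negative and 4 called over all genes, while adjusted over the list alone 7 passed, 1 of them higher. CD4 T cells were lower in the same list (adjusted p = 1.46e-06; adjusted p = 0.563 with an estimated correlation). Of its 16 members 13 were negative, 1 called over all genes and 10 over the list alone. In CD4 T cells Txk, a kinase of T cell signalling, fell from 131 CPM ± 14.3 to 64.6 CPM ± 9.39 (log2 -1.21, adjusted p = 0.0109), a call lost without young 2 (0.0888) and old 1 (0.0783). Satb1, a chromatin organizer, fell from 165 CPM ± 36.4 to 85.3 CPM ± 13.3 (log2 -1.11, adjusted p = 0.0445). It was called without young 3 (0.00102) and old 3 (0.0141) but not without young 1 (0.0592), young 2 (0.137), young 4 (0.0805), old 1 (0.169) or old 2 (0.161). Cst7, an inhibitor of granule proteases, rose from 117 CPM ± 19.6 to 226 CPM ± 26.4 (log2 0.77, adjusted p = 0.0326). It was not called without young 2 (0.0955), young 4 (0.0805), old 1 (0.0816) or old 2 (0.143). The exhaustion and checkpoint list rose in CD4 T cells (adjusted p = 0.000452; adjusted p = 0.563 with an estimated correlation). Of its 15 members 13 were positive, 0 called over all genes and 7 over the list alone. Its member Lag3 stood at 98.9 CPM ± 76.9 and 279.6 CPM ± 82.8. The median log2 change of this list was 0.59, and that of immunoglobulin genes in the same CD4 T cells 1.33 (adjusted p = 0.0101; adjusted p = 0.578 with an estimated correlation). The latter call was lost without young 3 and old 1, where its adjusted p reached 0.111. The largest cluster of CD8 T cells was 8 in young mice (45.5% ± 2.44, with 44.7% ± 8.92 in cluster 3) and 3 in old mice (57.0% ± 3.17). That of CD4 T cells was 9 in young mice (37.8% ± 13.4) and 5 in old mice (42.0% ± 3.92).

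Spleen B cells of old mice held more Lgals1 (ENSMUSG00000068220, mm10 chromosome 15, 78926725 to 78930465), which encodes the lectin galectin 1, at 134 CPM ± 52.96 against 37.4 CPM ± 5.89 in young mice (log2 1.77, adjusted p = 0.00413). Apoe (ENSMUSG00000002985, mm10 chromosome 7, 19696109 to 19699188), a lipid carrier, rose from 360.1 CPM ± 90.3 to 1223 CPM ± 712 (log2 1.70, adjusted p = 0.0183). Zbtb20 rose from 139.6 CPM ± 24.6 to 328 CPM ± 135 (log2 1.17, adjusted p = 0.0183). Lgals1 was called without each animal in turn (adjusted p of at most 0.0329), while Apoe and Zbtb20 were not called without young 2 (0.0884 and 0.0919) or young 4 (0.0894 for both). Dph5 fell from 66.6 CPM ± 5.89 to 40.7 CPM ± 4.35 (log2 -0.76, adjusted p = 0.0141), a call lost without young 4 (0.0738). The calls of Apoe, Zbtb20 and Dph5 were also lost with replicate number as a block and with the second term for another split. Those of Zbtb20 and Dph5 were lost with at most 100 cells as well. Fgl2, which the rule named because it was called in B cells and CD8 T cells, rose from 3.73 CPM ± 2.17 to 24.3 CPM ± 7.52 in B cells (log2 2.77, adjusted p = 0.00537). The age-associated B cell list rose (adjusted p = 1.77e-09; adjusted p = 0.233 with an estimated correlation). Of its 17 members 15 were positive, 8 called over all genes and 13 over the list alone. Its median log2 change was 1.17. Lists of other cell types moved in these B cells too, the effector memory list by 0.72 (adjusted p = 1.09e-05; adjusted p = 0.121 with an estimated correlation) and the naive T cell list by -0.39 (adjusted p = 0.00104; adjusted p = 0.167 with an estimated correlation). The tubule injury list rose by 0.89 (adjusted p = 0.000142; adjusted p = 0.141 with an estimated correlation). The largest B cell cluster was 1 in young mice (37.1% ± 18.7, and 14.8% ± 6.11 in old) and 0 in old mice (40.5% ± 15.6, and 29.9% ± 15.7 in young), and cluster 2 held 16.9% ± 4.11 and 7.10% ± 3.88. Clusters 4 and 7 held 1.91% ± 1.72 and 2.37% ± 0.889 of the B cells of young mice and 16.9% ± 2.42 and 12.9% ± 15.1 of those of old mice. Cluster 7 held 30.3% in old 2 but 3.86% and 4.47% in old 1 and old 3. With the cells of both left out, a choice made after seeing the data, 0 of the 117 B cell calls remained. Clusters follow expression, so leaving out these cells also takes away the genes that mark them.

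**Figure D2:**
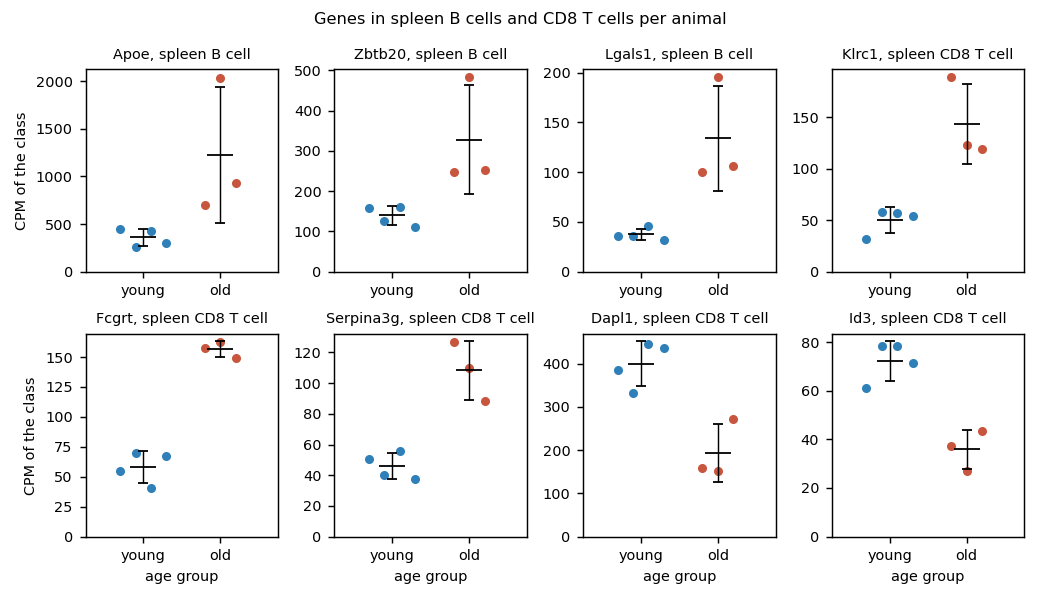
CPM of genes called in spleen B cells and CD8 T cells, 1 point per animal, with young (n = 4) and old (n = 3) side by side and bars for mean and SD. Klrc1 in CD8 T cells averages 50.2 CPM in young and 144 CPM in old, and Lgals1 in B cells 37.4 and 134 CPM.

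Spleen NK cells of old mice were lower in immediate early genes (adjusted p = 1.01e-10; adjusted p = 0.175 with an estimated correlation). Of its 20 members 17 were negative and 5 called over all genes, while adjusted over the list alone 16 passed, 1 of them higher. Zfp36 (ENSMUSG00000044786, mm10 chromosome 7, 28376784 to 28380253), which promotes decay of inflammatory transcripts, fell from 491 CPM ± 174 to 157 CPM ± 8.96 (log2 -1.68, adjusted p = 0.00117). It kept its call without each animal in turn and lost it with replicate number as a block (0.0671) and on the first lane alone (0.315). Nr4a1, a nuclear receptor gene induced by stimulation, fell from 222 CPM ± 44.7 to 63.5 CPM ± 30.6 (log2 -1.75, adjusted p = 0.00486), a call lost without old 1 (0.0992), and DESeq2 gave it no adjusted p. The chemokine gene Ccl4 fell from 3417 CPM ± 1404 to 1408 CPM ± 327 (log2 -1.30, adjusted p = 0.00999), a call lost without young 4 (0.0988) and old 1 (0.102). The calls of Nr4a1 and Ccl4 were also lost with replicate number as a block and on the first lane alone. That of Nr4a1 was lost with the second term for another split as well. In spleen monocytes, compared 3 against 3, H3f3b (ENSMUSG00000016559, mm10 chromosome 11, 116021912 to 116027962) fell from 3815 CPM ± 102 to 1999.7 CPM ± 363 (log2 -1.04, adjusted p = 0.00403), with adjusted p of at most 0.0427 without 1 animal. Its call was lost on the first lane alone (0.0709). With the second term for another split the change was log2 -0.76, a value that rests on old 3 as the only old animal. The largest monocyte cluster was 20 in young mice (54.6% ± 8.46, and 41.2% ± 9.47 in old) and 17 in old mice (58.8% ± 9.47, and 45.4% ± 8.46 in young). In NK cells H3f3b fell from 4515 CPM ± 1398 to 2317 CPM ± 497 (log2 -1.03, adjusted p = 0.0253), and was not called without young 2 (0.0646), young 3 (0.0679), young 4 (0.12) or old 1 (0.258). There its call was also lost with replicate number as a block, on the first lane alone and with the second term for another split (0.209). Cytosolic ribosomal protein genes fell in 5 of 6 spleen classes, with 79 of 81 members negative in CD4 T cells (adjusted p = 1.73e-27; adjusted p = 0.563 with an estimated correlation). In CD8 T cells the same number were negative (adjusted p = 3.60e-19; adjusted p = 0.531 with an estimated correlation).

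Over the 6 spleen classes edgeR called 166 genes higher and 68 lower in old mice, in B cells (110 and 7), CD8 T cells (39 and 18), monocytes (11 and 29), NK cells (3 and 10) and CD4 T cells (3 and 4). Dendritic cells had 0 calls, with 308 genes at an unadjusted p under 0.05, and DESeq2 called 2 higher and 0 lower in them. Without young 1, 2, 3 and 4 the spleen counts were 112, 37, 193 and 47 higher and 89, 41, 66 and 19 lower. Without old 1, 2 and 3 they were 109, 136 and 248 higher and 47, 55 and 147 lower. Calls kept without each animal in turn were 13 of 117 in B cells, 14 of 57 in CD8 T cells, 3 of 40 in monocytes, 2 of 13 in NK cells and 0 of 7 in CD4 T cells. Of the list tests 52 of 140 were called, 33 upward and 19 downward, 0 of them with an estimated correlation. Without young 4, 25 were upward and 12 downward.

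Genes of MHC class I presentation, which load and display peptides from inside the cell, rose in most classes of each tissue. The list was called upward in 13 of 14 lung classes, 7 of 9 kidney classes and 4 of 6 spleen classes. In lung fibroblasts 16 of 19 members were positive, with 0 called over all genes and 7 over the list alone (adjusted p = 1.81e-06; adjusted p = 0.301 with an estimated correlation). H2-D1, a class I heavy chain, stood at 1109 CPM ± 93.8 in young and 1760.05 CPM ± 216 in old. In type II pneumocytes 15 of 16 members were positive, with 4 called over all genes and 5 over the list alone (adjusted p = 1.33e-06; adjusted p = 0.327 with an estimated correlation). Among them H2-K1, chosen after its values were seen, rose from 618.5 CPM ± 38.8 to 937 CPM ± 119.5 (log2 0.71, adjusted p = 0.0115). In kidney B cells 17 of 17 members were positive, with 0 called over all genes and 7 over the list alone (adjusted p = 2.89e-07; adjusted p = 0.0945 with an estimated correlation). Tap1, a peptide transporter, stood at 60.7 CPM ± 17.7 and 142 CPM ± 49.3. In kidney proximal tubule 15 of 15 members were positive, with 0 called over all genes and 14 over the list alone (median log2 1.37, adjusted p = 5.47e-10; adjusted p = 0.371 with an estimated correlation). There old 1 stood apart, with B2m at 1794 CPM against 261 and 517 in old 2 and old 3 and 212 to 308 in young mice. Without old 1 the list was called upward in 4 kidney classes and downward in 1, and in 1 spleen class. In lung 11 to 14 classes were called upward without any 1 animal. MHC class II genes rose in 4 of 6 kidney, 7 of 12 lung and 2 of 5 spleen classes, and in spleen in 1 class without young 4 or old 3. In kidney endothelial cells, where class II genes were called, abundant B cell transcripts rose more (log2 2.53 against 1.83, medians relative to all genes). The interferon response list rose in 5 of 8 kidney, 8 of 14 lung and 3 of 6 spleen classes, and without old 1 in 1 kidney class (and fell in 2), 3 lung classes and 2 spleen classes. Without young 3 or young 4 it rose in 3 kidney classes, and without old 2 in 5 spleen classes. The direction of each of these lists was the same with RLE scaling and with library totals.

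**Figure D3:**
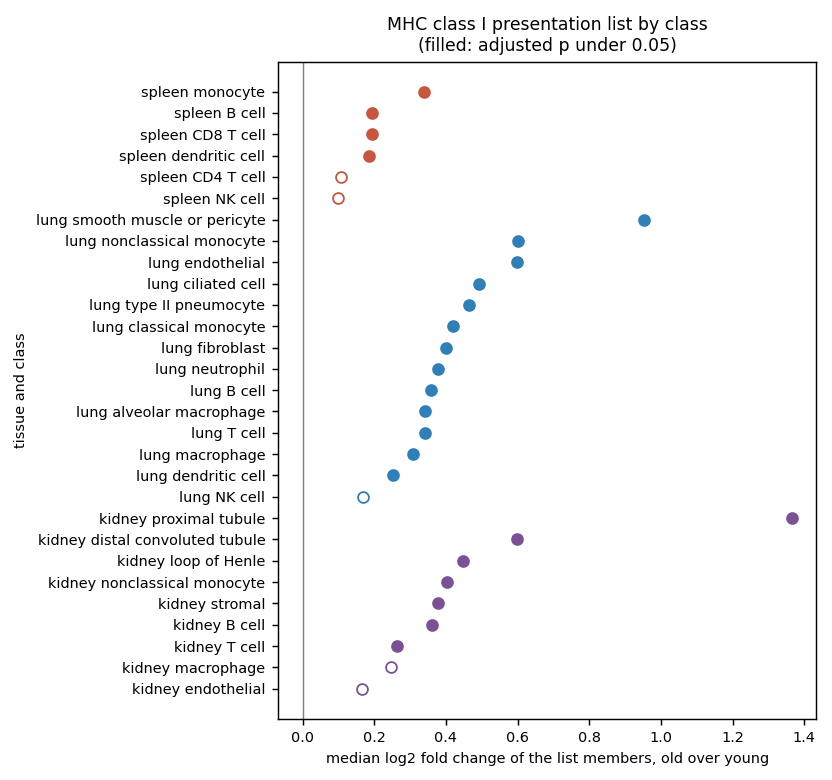
Median log2 fold change, old over young, of the MHC class I presentation list in each tested class of kidney, lung and spleen, 1 point per class, filled where the list was called. The list is called upward in 7 of 9 kidney, 13 of 14 lung and 4 of 6 spleen classes at the preset correlation.

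The age effect differed between tissues for 8 genes in the fits with animal as a block. Trdc in T cells stood at 62.6 CPM ± 32.4 in young and 172 CPM ± 75.3 in old kidney, and at 62.6 CPM ± 8.75 and 26.1 CPM ± 13.2 in spleen. Cluster 25, whose markers match gamma delta T cells, held 6.86% ± 3.07 of kidney T cells in young and 11.3% ± 4.30 in old mice. Its age effect was higher in kidney than in spleen (log2 difference of spleen from kidney -2.95, adjusted p = 0.000194, and at most 0.0113 without 1 animal). In kidney against spleen T cells Actn2 (-2.75, adjusted p = 0.0372) and Areg (2.40, adjusted p = 0.0372) were also called. In lung against spleen the calls were Cxcl2 (2.88, adjusted p = 0.0147), Mt1 (2.72, adjusted p = 0.0147) and Gata3 (1.06, adjusted p = 0.0458) in T cells. The same pair gave Timp2 (3.24, adjusted p = 0.00928) in B cells and Nfkbia (-1.40, adjusted p = 0.0272) in NK cells. Some of these rest on low levels in spleen. Timp2 stood at 1.27 CPM ± 0.797 in young and 11.1 CPM ± 7.77 in old spleen B cells. In lung B cells it stood at 17.6 CPM ± 14.6 and 14.3 CPM ± 8.99. In young and old spleen T cells Mt1 stood at 3.53 CPM ± 1.43 and 7.65 CPM ± 2.38, and Areg at 3.89 CPM ± 2.18 and 12.3 CPM ± 7.91. Cxcl2 in lung T cells stood at 98.7 CPM ± 33.6 in young and 24.2 CPM ± 10.3 in old, and in spleen T cells at 2.58 CPM ± 1.71 and 5.49 CPM ± 0.884. The call of Cxcl2 was lost without young 2 (0.140), young 3 (0.0692) and old 2 (0.105). That of Mt1 was lost without young 2 (0.149), young 3 (0.0692), old 1 (0.0733) and old 2 (0.139). That of Timp2 was lost without young 2 (0.104), young 4 (0.0904) and old 2 (0.156), and that of Nfkbia without young 3 (0.0920), old 1 (0.188) and old 3 (0.1002). Gata3 was kept without young 1 alone (0.0146) and reached 0.422 without old 1. Actn2 was kept without young 3 (0.00830) and old 3 (0.0182), Areg without these (0.00830 and 0.00411) and young 1 (0.0345), and both reached 0.575 without old 2. Kidney against lung gave 0 calls by edgeR, with 252, 312, 267 and 530 genes at an unadjusted p under 0.05 in B cells, T cells, macrophages and endothelial cells. It gave 3 without young 1, 1 without young 2 and 3 without old 1. DESeq2 was not run for this test. Without the block on animal 0 genes were called for each pair of tissues, and Trdc had an adjusted p of 0.207. Without young 1, 2, 3 and 4 and old 1, 2 and 3 the counts were 15, 2, 15, 1, 2, 4 and 6 for kidney against spleen and 47, 3, 1, 3, 5, 4 and 19 for lung against spleen.

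Immune cells together made up 63.1% ± 5.72 (SD, n = 3) of the cells of old lungs and 37.5% ± 10.1 (SD, n = 4) of young ones, higher in each old animal than in any young one. Neutrophils made up 5.95% ± 1.46 and 1.93% ± 0.697, and classical monocytes 8.55% ± 3.55 and 3.22% ± 1.96 (for all 3, exact permutation p = 0.0286, the smallest the design allows; adjusted p = 0.190). Endothelial cells made up 20.7% ± 3.30 of old and 29.2% ± 4.93 of young lungs and smooth muscle or pericytes 1.37% ± 0.234 and 3.91% ± 1.61 (exact permutation p = 0.0571 for both). Fibroblasts made up 8.01% ± 0.635 and 21.9% ± 15.4 (exact permutation p = 0.114). Without young 1 the young means were 42.3% for immune cells, 1.94% for neutrophils, 4.17% for classical monocytes, 30.9% for endothelial cells, 3.17% for smooth muscle or pericytes and 14.4% for fibroblasts. The groups did not overlap in any of these 6 (exact permutation p = 0.1, the smallest for 3 against 3). In kidney T cells made up 11.4% ± 3.40 of old and 4.29% ± 1.99 of young samples and nonclassical monocytes 4.34% ± 1.37 and 2.18% ± 0.831 (exact permutation p = 0.0286 for both, adjusted p = 0.243). In spleen erythroid cells made up 0.234% ± 0.0122 of old and 0.922% ± 0.376 of young samples (exact permutation p = 0.0571, adjusted p = 0.499). EdgeR on cell counts called spleen erythroid cells lower (log2 -1.99, adjusted p = 0.0188), kidney plasma cells higher (log2 4.30, adjusted p = 0.00322) and 0 lung classes. The kidney plasma cells numbered 2, 22 and 0 in old 1, 2 and 3 and 0, 0, 0 and 1 in young mice, so that call rested on old 2 (exact permutation p = 0.143). Young and old samples did not overlap in 2 of 17 kidney classes, 6 of 20 lung classes and 1 of 12 spleen classes, where chance gives 5.71%. In kidney and lung these counts take immune cells together as a class, a sum over other classes. In lung that sum is among the 6. Shares of a sample also add up to a fixed whole, so a rise in some classes lowers others. The classes are therefore not independent, and their number cannot be set against 5.71% as separate tests. The lower endothelial, fibroblast and smooth muscle or pericyte shares in lung cannot be told apart from the higher immune share. In the permutation test 0 classes passed the adjusted threshold, which a single class could not pass with so few animals. Without the library labelled young 1 lung 7 lung classes did not overlap, 4 higher and 3 lower. Over the fits without 1 animal the counts ran from 2 to 5 in kidney, from 6 to 11 in lung and from 1 to 3 in spleen. Kidney had 3, 2, 5 and 3 without young 1, 2, 3 and 4 and 5, 3 and 5 without old 1, 2 and 3. Lung had 9 without young 3 and 11 without old 1, and spleen had 3 without old 1 and 2 without young 3, old 2 or old 3. Shares depend on how cells survive dissociation, which the files do not record.

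**Figure D4:**
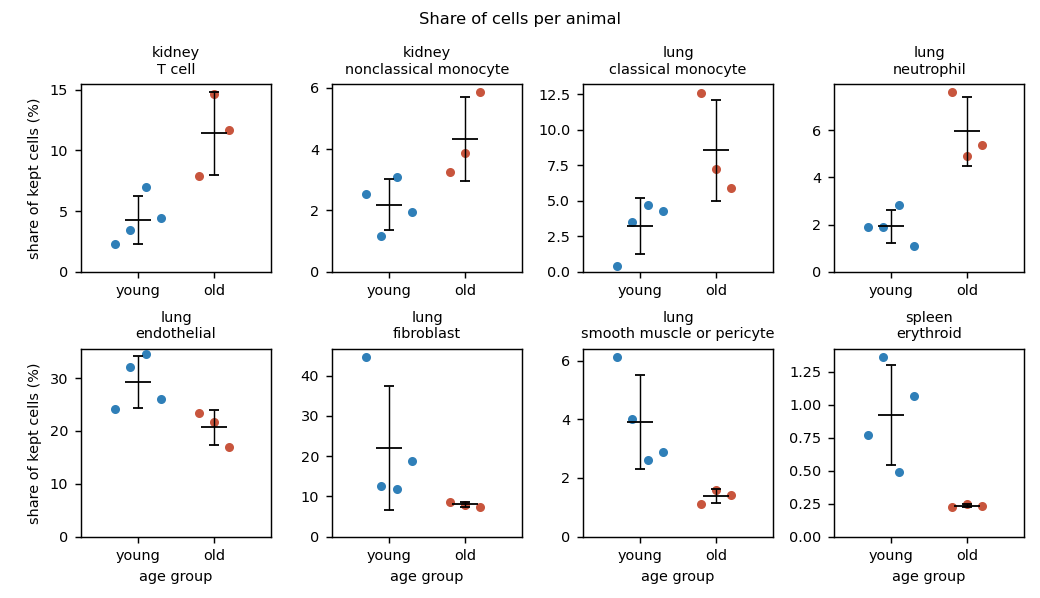
Share of kept cells in percent for classes of kidney, lung and spleen, 1 point per animal, with young (n = 4) and old (n = 3) side by side and bars for mean and SD. Neutrophils average 1.93% in young and 5.95% in old lungs.

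The spread between cells of 1 type was compared by exact permutation, a test in which a single class could not pass after adjustment with so few animals. In lung B cells the median distance of a cell to the others was 0.356 ± 0.00395 (SD, n = 3) in old and 0.343 ± 0.00551 (SD, n = 4) in young mice (exact permutation p = 0.0286, adjusted p = 0.4). In alveolar macrophages it was 0.463 ± 0.00492 in old and 0.473 ± 0.00350 in young, and in neutrophils 0.488 ± 0.00207 and 0.506 ± 0.0129. Both were compared 3 against 3 (exact permutation p = 0.1, the smallest for that size; adjusted p = 0.467). Groups without overlap were found in 3 lung classes, in 0 of 9 kidney classes and in 0 of 6 spleen classes. Without 1 animal the counts were 5 (without young 1) and 1 (without old 3) in kidney, 1 (without young 3) and 2 (without old 3) in spleen, and 0 without each of the others in both tissues. In lung they were 5 without young 2 and 3 or 4 without each of the others.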

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

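The tests of depth and of missing epithelium for the library labelled young 1 lung, the tests of that library alone and of handling stress for the other split of the animals, the test without B cell clusters 4 and 7, and all counts of splits were chosen after the results were seen. The tests of other tissue, of thinned sums and of free RNA were written before. Of 103 groups of 4 young animals, 8 held a sample far from the others, and chance alone gives about 1 in 20, or 5.15.

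The sample far from the others was young 4 for the kidney plasma cell share (0.0451%, against 0 in the others), young 3 for the kidney stromal share (3.14%, against 2.13% to 2.30%). It was young 1 for the lung NK cell share (0.714%, against 2.08% to 2.10%) and the lung macrophage share (7.20%, against 0.673% to 0.797%). Young 1 also stood apart in the cell-to-cell distance of lung fibroblasts (0.408, against 0.475 to 0.486) and in Klrc1 of spleen CD8 T cells (31.7 CPM, against 54.0 to 58.1). Young 2 stood apart in Gzmm of lung T cells (40.0 CPM, against 18.5 to 19.9) and in Vps37b of spleen CD4 T cells (78.4 CPM, against 109 to 114). The age effect differed between kidney and spleen T cells, as the log2 difference of spleen from kidney, for Trdc (-2.95), Actn2 (-2.75) and Areg (2.40). Between lung and spleen it differed for Timp2 in B cells (3.24), for Nfkbia in NK cells (-1.40), and in T cells for Cxcl2 (2.88), Mt1 (2.72) and Gata3 (1.06). The second lane of kidney of old 1, from which no cell was kept, held 8119 UMIs.

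The library labelled young 1 lung had almost no epithelial transcripts. Low depth is argued against by its total of 18381140 UMIs, where the lowest of the other lungs had 8743509 and held them. Loss of epithelial cells alone from an ordinary lung suspension was weighed by the other cells of this library. Of its endothelial cells 84.3% lay in cluster 14, which held at most 1.16% in the other lungs. Yet old 1 lung, with Sftpc at 15485 CPM, had 59.3% of its endothelial cells in cluster 11, which held at most 7.67% in the others. A cluster of its own in 1 class therefore decides little. But young 1 also had 98.4% of its fibroblasts in cluster 4 (at most 4.46% in the other lungs). Of its smooth muscle cells or pericytes 82.3% lay in cluster 29 (at most 5.58%). Old 1 had 1.48% of its fibroblasts in cluster 4. B cells of young 1 lay with those of the others, 93.8% of them in cluster 1. With 0 alveolar macrophages as well, these values argue against a loss of epithelial cells alone. Tissue other than lung remained possible, with the summed CPM of a marker list up to 18.9 times the highest of the other lungs, in the cartilage list, a value that rests on Comp alone (116 CPM against at most 0.544, while Col2a1 stood at 0). The heart muscle list was 3.63 times, fat 2.80, skeletal muscle 2.08, thymus 0.280 and liver 0.0181 times that level, sums in which single genes weigh most. Counted by gene, 7 of 8 heart muscle genes stood above all other lungs, by 5.87 to 367 times, and Actc1 did not. In the thymus list 3 of 5 did (Rag1, Dntt and Ptcra), in fat 2 of 6, in skeletal muscle 2 of 5, in cartilage 1 of 4 and in liver 0 of 5. A candidate explanation is a mislabelled or mixed sample that held heart or other tissue, which these files could not settle. A difference among young mice was not tested.

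A split of the animals other than by age, young 1, old 1 and old 2 against the rest, gave 519 calls over the 3 tissues. Age gave 389, and the next split, young 2, 3 and 4 against the rest, gave 353. In classes fitted without young 1 that next split is age with the signs swapped, so its calls there are those of age. Of the 519 calls 440 lay in lung, 191 of them in B cells. In spleen this split gave 58 calls and age 234. This may point to a structure of the samples that the labels do not name. Of the calls 44.5% lay in fits without the library labelled young 1 lung. But 152 of those 231 calls lay in lung classes without young 1. There the split sets old 1 and old 2 against old 3 and the young mice, which largely overlaps age. Kidney gave 21 calls, all in fits with young 1, so the lung library alone cannot account for every call. What share it accounts for was not decided. Stress in handling could not be decided. Of the calls 6.94% were of the immediate early and heat shock lists, against 0.701% by chance. These lists hold 46 genes, so they could make up few of the calls whatever the cause. In lung B cells 41 of them were tested, against 191 calls. Unequal depth and the structure could not be told apart. With sums thinned to the same total 14.5% of its calls remained, and 8.74% of those of age, so thinning removed most calls of either kind. A batch of processing may lie behind this split. With it as a second term all 389 calls of age kept their sign. The number kept is not given, since in classes fitted without young 1 this term leaves old 3 alone against the young mice.

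Spleen B cells had the most genes higher in old. The same genes moved less in CD4 T cells, with a median log2 change of 0.35 against 1.15 over 58 genes, a ratio of 0.305. That ratio lies under the limit set beforehand against free RNA. But the genes were chosen for their rise in B cells, which by itself makes a smaller change elsewhere likely. Only 58 of the 110 genes called higher could be tested in CD4 T cells. Free RNA was therefore not excluded. More cells of cluster 4 in old spleens (14.1% to 18.3%, against 0.0332% to 3.44% in young), and of cluster 7 in old 2 alone (30.3%), could not be told apart from a change in B cells at large. With the cells of both clusters left out 0 of 117 calls remained, and the median log2 change of the genes called higher went from 1.67 to 0.28, but clusters follow expression and these were chosen for their rise, so this decides nothing. An effect of age on the number of these cells, or on B cells at large, stays open as untested.

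How often other splits of the 7 animals into 4 and 3 gave as many calls was counted over 35 splits, the real one included. In spleen 1 split gave as many genes higher (166, highest other 72), genes lower (68, highest other 65) and lists (52, highest other 50). In lung 1 split gave as many lists (109, highest other 97). For these 4 counts that split was the real one. The smallest p of such a permutation over 35 splits is 0.0286, which cannot pass 0.05 after adjustment over the counts compared. Chance was therefore not excluded for these 4 counts. Splits with as many calls numbered 10 for kidney genes higher (4, highest other 17) and 5 for kidney genes lower (5, highest other 20). For kidney lists they numbered 4 (72, highest other 76). In lung they numbered 3 for genes higher (64, highest other 161) and 3 for genes lower (82, highest other 279). The 35 splits include young 2, 3 and 4 against the rest, which repeats age with signs swapped in classes without young 1. For age effects that differed they numbered 18 in kidney against spleen (3, highest other 56) and 6 in lung against spleen (5, highest other 261). Chance was not excluded for any of these counts either. In kidney against lung the real split gave 0 calls, which all 35 splits match (highest other 43), so that count decides nothing.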

How the results depend on the processing

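The split term, B cells without clusters 4 and 7 and scaling by library totals were chosen after seeing the data; the other alternatives were planned. Of 993 alternative values of the named genes, 674 kept their direction and their call, 316 kept the direction and lost the call, and 3 reversed: with B cell clusters 4 and 7 left out, Apoe (-0.12), Lgals1 (-0.20) and Zbtb20 (-0.10) in spleen B cells. Genes higher in old numbered 40 in kidney with DESeq2. Without a gene filter they numbered 440 in kidney, 727 in lung and 742 in spleen, and genes lower 203, 740 and 331. With DESeq2 genes lower numbered 40 in kidney, 139 in lung and 107 in spleen. With replicate number as a block genes higher numbered 18, 13 and 34 in the 3 tissues, genes lower 12 in lung and 14 in spleen, and lists called 60 in lung and 33 in spleen. The block was fitted in 9 of 14 lung and 5 of 6 spleen classes, in which 24 and 194 genes were called without it and 25 and 48 with it. Replicate numbers did not pair animals throughout, since 0 of 23 classes had every pair correlated over 0.1. Single pairs did match, with 16 of 69 correlations over 0.1 and values from -0.197 to 0.323. In 26 of 69 the old animal was best matched by the young one of its own number. In each kidney class old 1 was best matched by young 1. The first lane alone gave 15, 10 and 60 genes higher and 11, 23 and 10 lower. With at most 100 cells genes higher numbered 35 in lung and 29 in spleen, and genes lower 3 in kidney and 48 in lung. With doublets kept kidney had 7 higher, and at resolution 2 it had 14 higher and 13 lower. The split term gave 38 higher in lung, 48 higher and 20 lower in spleen, and 201, 5 and 25 genes whose age effect differed in kidney against lung, kidney against spleen and lung against spleen. Without a gene filter these were 55, 19 and 128, and without the block on animal 0 for kidney against spleen and lung against spleen. With B cell clusters 4 and 7 left out spleen had 56 genes higher, 0 of them in B cells. Camera with an estimated correlation called 0, 0 and 0 lists, and fry 3, 7 and 10. EdgeR on cell counts called 1 kidney class, 0 lung classes and 1 spleen class. Distances over 200 genes gave 1 class in lung and 1 in spleen, and with doublets kept 1 in lung. Without 1 animal, genes higher ran from 2 to 76 in kidney, 27 to 148 in lung and 37 to 248 in spleen, and genes lower from 1 to 36, 18 to 212 and 19 to 147. Age effects that differed ran from 0 to 3 for kidney against lung, 1 to 15 for kidney against spleen and 1 to 47 for lung against spleen. Lists ran from 58 to 86, 88 to 108 and 37 to 56, shares without overlap from 2 to 5, 6 to 11 and 1 to 3, and distances without overlap from 0 to 5, 3 to 5 and 0 to 2. Of 233 called lists, all medians kept their sign with RLE and 231 with library totals, the exceptions being the nuclear respiratory chain in distal convoluted tubule (-0.16 to 0.04) and mitochondrially encoded transcripts in spleen CD4 T cells (-0.16 to 0.03). Relative to the median of all genes, which library totals moved as well, 0 of the 233 changed side. Library totals moved the median of all genes by over 0.1 in 7 classes, by up to 0.188 in spleen CD4 T cells, and RLE by at most 0.0222. Fits with no filter test more genes, and those on 1 lane, 100 cells or fewer animals hold fewer counts. The first lane alone could be tested in 7 of 9 kidney and 11 of 14 lung classes. Of the 53 named genes 43 lost their call without at least 1 animal and 7 with DESeq2, which gave 5 of them no adjusted p. Other settings could not be run for all of them. The call was lost for 35 of 49 on the first lane alone, 22 of 51 with at most 100 cells and 19 of 32 with the replicate block. Why DESeq2, resolution 2 and kept doublets moved the counts was not tested. Of genes changed 2-fold in simulated data, 7.00% to 61.0% were recovered per kidney class, and what sets this share was not tested.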

Other observations

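Genes in these paragraphs were chosen after their values were seen, and no further hypothesis was tested here. Spleen monocytes of old mice, compared 3 against 3, were lower in Hspa1b, an inducible chaperone, which fell from 125 CPM ± 44.1 to 21.6 CPM ± 12.2 (log2 -2.58, adjusted p = 0.00403) and was called without each animal in turn. The interferon response list rose in them (adjusted p = 2.79e-05; adjusted p = 0.450 with an estimated correlation). Of its 24 members 23 were positive, 1 called over all genes and 5 over the list alone. The largest cluster of these monocytes differed between young (20) and old (17). In spleen CD8 T cells S100a6, a calcium-binding protein, rose from 339 CPM ± 99.0 to 769 CPM ± 55.6 (log2 1.05, adjusted p = 0.00189) and Actn1, an actin crosslinker, fell from 118 CPM ± 9.84 to 64.0 CPM ± 2.82 (log2 -1.01, adjusted p = 0.000874), both called without each animal in turn. In spleen B cells Lgals3, which encodes galectin 3, rose from 15.2 CPM ± 3.47 to 52.5 CPM ± 7.57 (log2 1.70, adjusted p = 0.00159), also without each animal in turn. The NF-kB and inflammatory signalling list fell in spleen NK cells (adjusted p = 1.40e-05; adjusted p = 0.140 with an estimated correlation). Of its 10 members 9 were negative, 2 called over all genes and 6 over the list alone.

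The ER chaperone list rose in lung B cells (adjusted p = 3.42e-05; adjusted p = 0.312 with an estimated correlation). Of its 25 members 23 were positive, 0 called over all genes and 3 over the list alone. Lysosomal genes rose in kidney macrophages (adjusted p = 0.0123, and 0.0677 without old 1; adjusted p = 0.310 with an estimated correlation). Of its 35 members 26 were positive. Their member Ctsd, a protease, stood at 191 CPM ± 80.6 in young and 517 CPM ± 207 in old. The proteasome list rose in 4 of 9 kidney, 4 of 14 lung and 4 of 6 spleen classes, and in 0 kidney classes without old 2, 2 without old 1 or young 3, 2 lung classes without old 1, 1 without young 4 and 2 spleen classes without young 4. Mitochondrially encoded transcripts fell in 6 of 9 kidney, 8 of 14 lung and 3 of 6 spleen classes, with a median in spleen CD4 T cells of -0.16 (0.03 with library totals, which moved the median of all genes there by 0.188). The list of senescence and p53 response genes was called in 0 of 9 kidney, 0 of 14 lung and 0 of 5 spleen classes with camera, and fry called 0 too; without 1 animal it was called in 1 class without old 2, in 2 without old 3 and in 1 lung class without young 1.

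In lung endothelial cells MHC class II genes rose (adjusted p = 2.55e-06; adjusted p = 0.730 with an estimated correlation). Of its 11 members 10 were positive and 0 called over all genes or over the list alone. Cd74, the invariant chain, stood at 1687 CPM ± 1166 in young and 9133 CPM ± 6069 in old, with 15548, 3483 and 8368 CPM in old 1, old 2 and old 3. In kidney proximal tubule Cd74 stood at 1511 CPM in old 1, 129 CPM in old 2 and 191 CPM in old 3, against 65.6 to 105 CPM in young mice. These cells lie next to immune cells rich in Cd74 in the same suspension, and free RNA was not modelled. Of the lung endothelial cells of old 1 59.3% lay in cluster 11, which held at most 7.67% in the other animals, and 84.3% of those of young 1 in cluster 14.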
